A study of Pseudoalteromonas sp. JSTW with 9 samples.

How the data were processed

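RNA sequencing measured transcript levels in 9 libraries of Pseudoalteromonas sp. JSTW, a marine bacterium whose source the labels give as marine sediment. The labels do not say whether each library came from its own culture, so the spread within a group may not be that between cultures. The labels place 3 libraries in each of 3 groups: untreated, an aerobic condition and an anaerobic condition. They give no medium, temperature, time or growth phase, and they do not say what untreated meant beyond the word. Cells were collected by centrifugation and frozen, RNA was extracted with Trizol, and libraries were made from 1 ug of total RNA with a TruSeq RNA kit. Whether the libraries kept the strand of the transcript is not given in the sources used here.

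The authors deposited 1 table of read counts per library over 4129 features: 4008 coding gene models, 71 additional transcripts and 50 small RNA predictions, all on a single sequence. The values were whole numbers of at least 0 with totals that differed between libraries, so they were used as raw counts. The submitters' processing notes name Bowtie2 2.2.3, HTSeq 0.6.1, DESeq 1.18.0, edgeR, Picard 1.96, SAMtools 0.1.18 and GATK, with no role or order. The genome build is not given in the sources used here. A table deposited for the whole series holds coordinates, annotation and, for each pair of groups, the authors' log2 fold change, their adjusted p-value and their call of up or down. That table also holds 18 per-library columns and 9 group-mean columns, which were not used in the analysis. Where both group means of read counts were above 0 (3999, 4000 and 4033 features in anaerobic against aerobic, aerobic against untreated and anaerobic against untreated), the authors' log2 fold changes differed from the log2 of their ratio by at most 0.000102, 0.000415 and 5e-05. Gene symbols are absent from it, so genes are named by their product text and feature identifier. Product text was present for 1824 features, orthology numbers for 1249 and Gene Ontology terms for 2810. Features overlap in 745 pairs, and 63 features had no count in any library.

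Total counts ranged from 5285046 to 6871967 per library. Counts were normalized with edgeR 4.0.16 (R 4.3.3) by TMM, features with low counts were removed with filterByExpr by group, and 3909 features were tested and 220 were not. Group differences were tested with edgeR's quasi-likelihood F-test in a single fit of all 9 libraries with 6 residual degrees of freedom, with Benjamini-Hochberg adjusted p under 0.05 and no minimum fold. The 3 pairwise comparisons and a joint test of any difference among the 3 groups were made. Errors of log2 fold changes are standard errors taken from the F statistic; levels are normalized CPM (counts scaled to library size) with the SD over 3 libraries.

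The groups, comparisons, tests, alternatives, gene lists and the rule for named genes were set before the data were examined. The 33 gene lists were patterns applied to product text; they held 573 distinct members, 32 of them in more than 1 list. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Named genes are, per comparison, the 8 highest and 8 lowest log2 fold changes among called genes with a mean log2 CPM of at least 4, product text and no overlap between the libraries of the groups; up to 4 called members of each list past its test and of 6 lists on respiration, stress and ribosomes; and the 5 most abundant features of each group. Genes named outside this rule are marked as such. Matching by words put some members into lists they do not serve, so curated lists, and a list of F-type ATPase subunits that the fixed pattern had missed, were added after the product texts were seen.

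Alternatives were median-of-ratios and upper-quartile factors, no filter on low counts, a filter of at least 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, leaving out the 20 most abundant features, fitting only the 6 libraries compared, and at least a 2-fold change. Leaving out untreated replicate 3 and anaerobic replicate 3 together, and using coding gene models alone, were added after the data were seen. All pairs of replicates differed by more than counting noise and were kept as separate samples. The method was tested on simulated data of 3909 genes with these dispersions: of 100 genes changed 4-fold, 91, 87 and 91 percent were called (anaerobic against aerobic, aerobic against untreated, anaerobic against untreated), of 100 changed 2-fold, 28, 31 and 34 percent, and false calls made up 3.3, 4.1 and 4.6 percent of calls. Far fewer genes were changed in these simulations than were called in the real comparisons. No reference genome was used.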

Results

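Transcript levels were measured by RNA sequencing in 9 libraries of the marine bacterium Pseudoalteromonas sp. JSTW, 3 untreated, 3 from an aerobic condition and 3 from an anaerobic condition. Total counts per library were 5362789, 5285046 and 5740829 in the untreated group, 6871967, 5918860 and 5445854 in the aerobic group, and 6126651, 6501867 and 5526105 in the anaerobic group. Between 3965 and 4038 features had at least 1 count in a library. Positions are bases on the only sequence named in the deposited annotation, whose build is not given in the sources used here.

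The feature with the most counts in the aerobic and anaerobic libraries was PW_GM002093, a 93-base coding gene model without product text (bases 2321088 to 2321180, minus strand). It took 9.01% ± 1.77 (SD, n = 3) of the counts in untreated, 38.2% ± 1.55 in aerobic and 52.0% (38.4% to 61.2%) in anaerobic libraries. Its fitted log2 fold change was 2.69 ± 0.62 (SE; adjusted p = 0.00418) in aerobic against untreated and 3.20 ± 0.64 (adjusted p = 0.002) in anaerobic against untreated, and the latter was 3.84 without untreated replicate 3. In anaerobic against aerobic it was 0.51 ± 0.59 (adjusted p = 0.505). PW_GM001175, a 105-base gene model without product text, took 10.2% ± 6.65 of the counts in untreated, 4.93% ± 0.238 in aerobic and 4.09% ± 1.76 in anaerobic libraries. Its share was 17.8% in untreated replicate 3, against 7.03% and 5.69% in the other untreated libraries. Its log2 fold changes against untreated did not pass the test, and without that library they turned from -0.57 to 0.60 (aerobic) and from -0.79 to 0.47 (anaerobic). A flagellin gene (PW_GM000887) took 0.996% ± 0.227 in untreated and 2.63% ± 0.151 in aerobic libraries. The 20 most abundant features together took from 25.9% (untreated replicate 2) to 72.6% (anaerobic replicate 2) of a library.

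**Figure D1:**
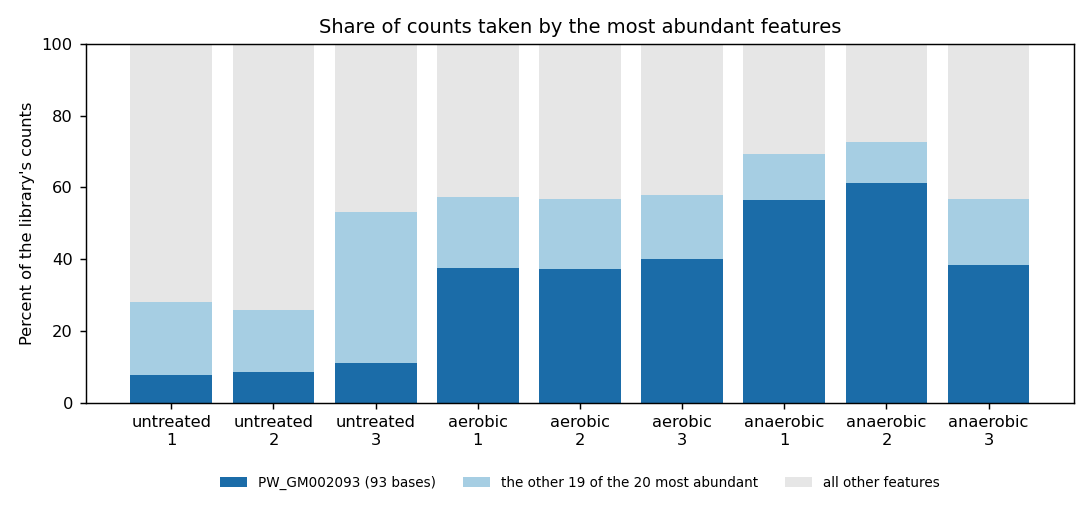
Percent of each library's counts (y axis) in the 9 libraries (x axis), split into PW_GM002093, the other features among the 20 most abundant, and all others. PW_GM002093 took at least 7.56% of the counts in untreated libraries, 37.2% to 40.0% in aerobic and 38.4% to 61.2% in anaerobic libraries.

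The groups separated on the first principal component of log2 CPM, which held 65.8% of the variance, and the second, with 20.3%, parted aerobic from anaerobic libraries. Within groups, untreated replicate 3 stood apart, where 606 of 3422 features (17.7%) lay at least 2-fold off the other untreated libraries, and anaerobic replicate 3, where 673 (19.7%) did; for aerobic replicate 3 the number was 52 (1.52%). The ribosomal protein genes moved with these libraries: their median was 9.03 and 9.06 log2 CPM in untreated replicates 1 and 2 and 6.88 in replicate 3, and 6.42, 5.97 and 7.36 in anaerobic replicates 1 to 3. Flagellar and chemotaxis genes had medians of 6.65, 7.26 and 7.75 in the anaerobic libraries, between 5.36 and 5.58 in untreated and between 8.25 and 8.36 in aerobic ones. Of 3909 features tested, 2923 (74.8%) differed among the 3 groups in the joint test.

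Anaerobic against aerobic compared the anaerobic with the aerobic condition named in the labels. As the labels give no medium, time or growth phase, no change here can be assigned to oxygen apart from these. Nitric oxide dioxygenase (PW_GM003086, bases 3433799 to 3434962), a flavohemoprotein that removes nitric oxide, had 1187 ± 730.3 CPM (SD, n = 3) in anaerobic and 4.06 ± 0.385 CPM in aerobic libraries, a log2 fold change of 8.19 ± 0.61 (SE; adjusted p = 3.43e-05). The cation/acetate symporter gene (PW_GM000676) rose by 6.66 ± 0.87 (adjusted p = 0.000639) and acetyl-CoA synthetase (PW_GM002279) by 4.76 ± 0.55 (adjusted p = 0.000318) on the log2 scale, while acetate kinase and phosphate acetyltransferase, of another route between acetate and acetyl-CoA, fell with -1.63 ± 0.16 and -1.47 ± 0.20. An Rrf2 family regulator of iron-sulfur cluster assembly (PW_GM000208) rose by 5.82 ± 0.30 (adjusted p = 6.73e-06) and a MerR family regulator (PW_GM002590) by 5.20 ± 0.53 (adjusted p = 0.000187). Genes for histidine breakdown fell, histidine ammonia-lyase (PW_GM003484) with a log2 fold change of -4.79 ± 0.46 (adjusted p = 0.000147) and urocanate hydratase (PW_GM003483) with -4.56 ± 0.41 (adjusted p = 0.000102). Histidine ammonia-lyase had 15.3 to 43.8 CPM in untreated, 2142 to 2498 in aerobic and 62.9 to 118 in anaerobic libraries. Its anaerobic levels thus lay above the untreated ones, and only the aerobic levels were high. The outer membrane receptor genes PW_GM001501, for iron complexes, and PW_GM002341, for ferric dicitrate, fell with -3.14 ± 0.20 and -3.46 ± 0.54. PW_GM001501 likewise had 58.1 to 71.0 CPM in untreated, 807 to 970 in aerobic and 92.7 to 117 in anaerobic libraries. The iron uptake and storage list did not pass its test (camera adjusted p = 0.792, and adjusted p = 0.876 with an estimated correlation). Of its 36 members 10 rose, 7 fell and 19 did not pass the test, also when adjusted over the list alone. Without anaerobic replicate 3 the log2 fold changes of nitric oxide dioxygenase, the symporter and acetyl-CoA synthetase were 7.55, 5.42 and 4.06, each still past the test.

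Of 98 features in the flagellar and chemotaxis list, 43 fell, 9 rose and 46 did not pass the test (camera adjusted p = 0.000229, direction lower; 43 lower and 10 higher when adjusted over the list alone; adjusted p = 0.776 with an estimated correlation). The list holds 11 additional transcripts that lie opposite flagellar genes of the same list; of its 87 coding genes 32 fell and 9 rose (camera adjusted p = 0.00188). Flagellin PW_GM000887 fell from 30710.0 ± 1996 to 9097 ± 3706 CPM, with a log2 fold change of -1.76 ± 0.37. Members that rose included MotA (PW_GM000924), a stator protein of the flagellar motor, with 2.37 ± 0.26, and a chemotaxis sensory transducer (PW_GM002157) with 3.38 ± 0.36. Without anaerobic replicate 3, 68 members fell and 10 rose. Of 51 features in the ribosomal protein list, 2 of them additional transcripts, 21 rose, 3 fell and 27 did not pass the test (camera adjusted p = 0.000285, direction higher; 21 and 3 when adjusted over the list alone; adjusted p = 0.817 with an estimated correlation; adjusted p = 0.122 with fry). S10 (PW_GM000171) rose by 3.92 ± 0.88 and L3 (PW_GM000172) by 3.72 ± 0.84 on the log2 scale, and by 2.75 and 2.83 without anaerobic replicate 3. Without untreated replicate 3, 34 of 52 members rose and 3 fell. The 3 that fell, named after their values were seen, were an L31 gene, a transcript of S20 and a methyltransferase of L3, which is not a ribosomal protein.

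The SOS response and DNA repair list had 9 of 11 members lower, 0 higher and 2 not past the test, also when adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.648 with an estimated correlation). RuvB (PW_GM001887), a helicase of Holliday junctions, had a log2 fold change of -1.24 ± 0.17, the helicase DinG (PW_GM001220) -1.05 ± 0.14 and RecN (PW_GM001939) -1.01 ± 0.17. Of 20 amino acid degradation genes, 9 fell, 1 rose and 10 did not pass the test (11 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.0225; adjusted p = 0.648 with an estimated correlation). The list median was 6.21 and 6.16 log2 CPM in anaerobic replicates 1 and 2 but 6.93 in replicate 3, where aerobic libraries had 6.93 to 7.05. Beside the histidine genes, 4-hydroxyphenylpyruvate dioxygenase (PW_GM002212), an oxygen-using enzyme of tyrosine breakdown, had -2.62 ± 0.55 and arginine N-succinyltransferase (PW_GM003635) -2.34 ± 0.26; the 1 that rose was alanine dehydrogenase, named here after its value was seen. In all, 1690 of 3909 features changed (43.2%), 818 higher and 872 lower. Of all 3909 features, called or not, 2200 (56.3%) had no overlap between the libraries of the groups, where chance gives 10%. The count was 1072 without aerobic replicate 1, 1105 without aerobic replicate 2 and 2900 with untreated replicate 3 and anaerobic replicate 3 both left out. Upper-quartile factors moved the median of all genes by 0.29 (log2) and gave 1067 higher and 561 lower.

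**Figure D2:**
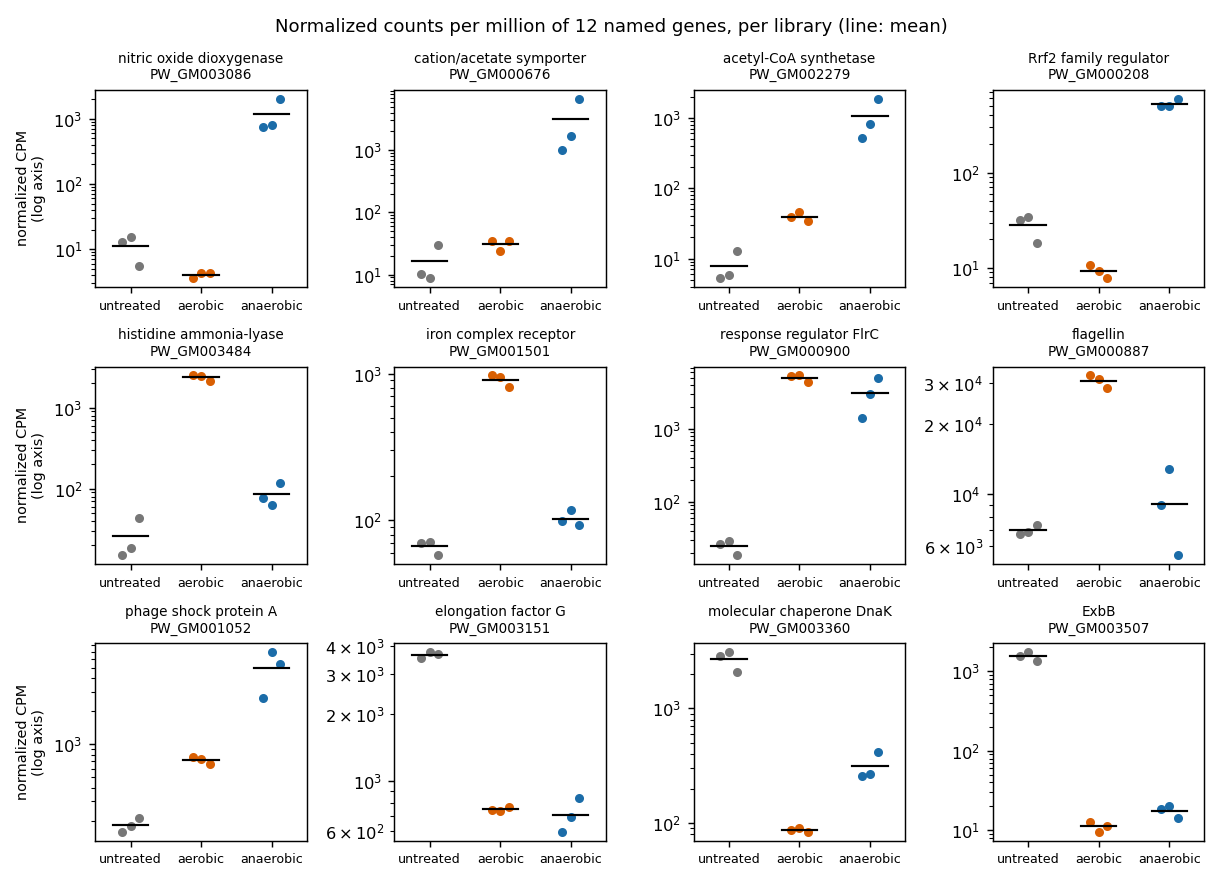
Normalized CPM (y axes, log scale) of 12 named genes in the 3 untreated, 3 aerobic and 3 anaerobic libraries (x axes); points are libraries and lines are group means. Nitric oxide dioxygenase averaged 11.3, 4.06 and 1187 CPM in the 3 groups, and ExbB 1554, 11.2 and 17.6 CPM.

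Aerobic against untreated compared the aerobic condition with the libraries labelled untreated. Genes of a flagellar cluster rose together: the sensor kinase FlrB (PW_GM000899) by 7.51 ± 0.66 (SE; adjusted p = 1.01e-05) and the response regulator FlrC (PW_GM000900, bases 984627 to 986033), which switches on flagellar genes, by 7.67 ± 0.55 (adjusted p = 3.36e-06) on the log2 scale. The basal body protein FliE (PW_GM000901) rose by 7.56 ± 0.51 (adjusted p = 2.78e-06). FlrC had 24.9 ± 5.60 CPM (SD, n = 3) in untreated and 5106 ± 525.5 CPM in aerobic libraries. An outer membrane protein (PW_GM002189) fell from 2141 ± 719 to 1.36 ± 0.288 CPM, with a log2 fold change of -10.61 ± 0.65 (adjusted p = 1.91e-06). The adjoining alkaline phosphatase genes PW_GM000345 and PW_GM000346, enzymes that release phosphate, had -9.30 ± 0.77 (adjusted p = 6.88e-06) and -7.44 ± 0.49 (adjusted p = 2.59e-06). Alanine dehydrogenase (PW_GM001743) had -7.33 ± 0.37 (adjusted p = 1.09e-06) and ExbB (PW_GM003507), which energizes outer membrane transport, -7.11 ± 0.28 (adjusted p = 4.97e-07). The labels give no medium, time or growth phase for any group, so no change against untreated can be assigned to the named condition apart from these.

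Of the 98 flagellar and chemotaxis features, 80 rose, 9 fell and 9 did not pass the test (82 and 10 when adjusted over the list alone; camera adjusted p = 3.44e-12; adjusted p = 0.324 with an estimated correlation). Without the 11 additional transcripts, 69 of 87 genes rose and 9 fell (camera adjusted p = 5.28e-10). Flagellin PW_GM000887 rose by 2.14 ± 0.38, and most of the 9 that fell were receptors of the methyl-accepting chemotaxis type, named after their values were seen. Type IV pilus features rose in 8 of 10 cases and fell in 1, a transcript of PilM named after its value was seen, with the same numbers when adjusted over the list alone (camera adjusted p = 0.0218; adjusted p = 0.324 with an estimated correlation). FimV (PW_GM002063) rose by 3.59 ± 0.34, a PilZ protein (PW_GM000760) by 4.46 ± 0.40 and PilY1 (PW_GM002168) by 3.61 ± 0.46. Extracellular peptidases rose in 15 of 18 cases and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.324 with an estimated correlation). The subtilisin-type peptidase PW_GM001941 rose by 4.26 ± 0.81 and peptidase M28 (PW_GM002062) by 2.85 ± 0.17; the 2 that fell, named after their values were seen, were DegS, a periplasmic stress protease, and a carboxypeptidase. SOS and DNA repair genes rose in 9 of 11 cases and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.365 with an estimated correlation). The repressor LexA (PW_GM003078) rose by 2.18 ± 0.16 and RuvC (PW_GM001889) by 2.13 ± 0.27. The 1 that fell was a putative resolvase, named after its value was seen. The list of prophage and mobile elements had 8 of 10 members higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.0264; adjusted p = 0.324 with an estimated correlation; adjusted p = 0.0944 with untreated replicate 3 and anaerobic replicate 3 left out). Most of its members were matched by the word phage alone and are phage shock proteins, a membrane stress system: PspA (PW_GM000420) rose by 3.11 ± 0.45 and phage shock protein C (PW_GM001054) by 2.11 ± 0.36.

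Ribosomal protein genes fell in 48 of 51 cases, 1 rose and 2 did not pass the test (49 and 1 when adjusted over the list alone; camera adjusted p = 5.75e-10; adjusted p = 0.444 with an estimated correlation). S10 had a log2 fold change of -6.48 ± 0.98 and L3 -6.39 ± 0.94; the 1 that rose was an L31 gene (PW_GM003675), named after its value was seen. Aminoacyl-tRNA synthetases and translation factors fell in 24 of 30 cases and rose in 0 (24 and 1 when adjusted over the list alone; camera adjusted p = 4.67e-05; adjusted p = 0.324 with an estimated correlation). Elongation factor Ts (PW_GM001068) had -3.32 ± 0.20 and elongation factor G (PW_GM003151) -2.30 ± 0.23. Of 13 glycolysis and gluconeogenesis genes, 12 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00052; adjusted p = 0.324 with an estimated correlation). Enolase (PW_GM002342) had -3.09 ± 0.19 and triosephosphate isomerase (PW_GM002108) -3.01 ± 0.24, and the member that rose was an aldolase of the Entner-Doudoroff pathway (PW_GM003738) with 2.42 ± 0.45. Phosphate uptake genes fell in 13 of 20 cases and rose in 5, also when adjusted over the list alone (camera adjusted p = 0.0218; adjusted p = 0.324 with an estimated correlation). A phosphate transport permease (PW_GM002977) had -5.52 ± 0.39. The 5 that rose, named after their values were seen, were a PhoH-like ATPase, an exopolyphosphatase, and response regulators OmpR and PhoP (in 2 copies), of which OmpR and PhoP are not known for phosphate uptake. Heat shock and protein quality genes fell in 14 of 26 cases and rose in 7 (14 and 8 when adjusted over the list alone; camera adjusted p = 0.0323; adjusted p = 0.75 with an estimated correlation; adjusted p = 0.0597 without anaerobic replicate 3). The chaperones GroES (PW_GM003029), HtpG (PW_GM001960), DnaK (PW_GM003360) and GrpE (PW_GM001935) had log2 fold changes of -5.70 ± 0.31, -4.95 ± 0.24, -4.94 ± 0.31 and -4.73 ± 0.25.

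In aerobic against untreated, 2297 of 3909 features changed (58.8%), 1139 higher and 1158 lower. Of all 3909 features, called or not, 2824 (72.2%) had no overlap between the libraries of the groups, where chance gives 10%. Leaving out single libraries gave 1984 to 2649.

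**Figure D3:**
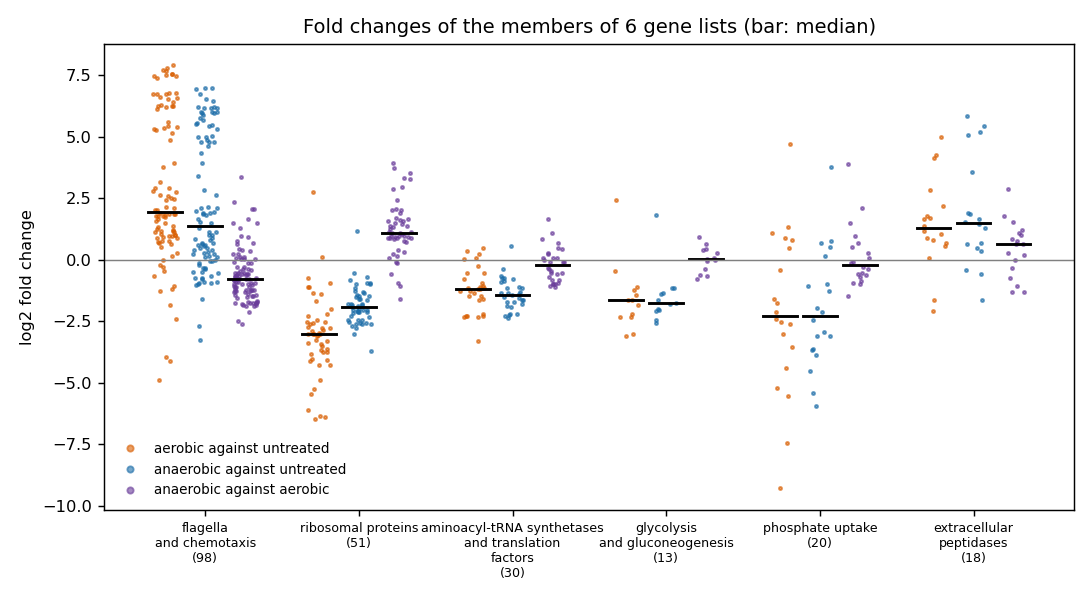
Log2 fold change (y axis) of the tested members of 6 gene lists (x axis, number of members in brackets) in the 3 comparisons; points are genes and bars are medians. The flagellar and chemotaxis features, 11 of them additional transcripts, had medians of 1.95, 1.38 and -0.78, and the ribosomal protein genes -3.01, -1.91 and 1.10, in aerobic against untreated, anaerobic against untreated and anaerobic against aerobic.

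Anaerobic against untreated compared the anaerobic condition with the same untreated libraries. The cation/acetate symporter (PW_GM000676) rose by 7.61 ± 0.91 (SE; adjusted p = 9.03e-05), acetyl-CoA synthetase (PW_GM002279) by 7.09 ± 0.61 (adjusted p = 1.49e-05) and nitric oxide dioxygenase (PW_GM003086) by 6.70 ± 0.56 (adjusted p = 1.22e-05) on the log2 scale. Flagellar genes rose here too, FlrC by 6.99 ± 0.54 (adjusted p = 9.7e-06) and the ring protein FliF (PW_GM000902) by 6.76 ± 0.51 (adjusted p = 8.34e-06). ExbB (PW_GM003507) fell from 1554 ± 192 to 17.6 ± 2.94 CPM (SD, n = 3), a log2 fold change of -6.46 ± 0.27 (adjusted p = 8.01e-07). Alanine dehydrogenase (PW_GM001743) had -6.35 ± 0.35 (adjusted p = 3.37e-06), alkaline phosphatase PW_GM000346 -5.95 ± 0.46 (adjusted p = 9.76e-06) and a TonB-dependent receptor (PW_GM003501) -5.35 ± 0.28 (adjusted p = 2.39e-06). The same limit of the labels holds for these changes as for aerobic against untreated. Without anaerobic replicate 3 the symporter, acetyl-CoA synthetase and nitric oxide dioxygenase stood at 6.38, 6.40 and 6.04, and without untreated replicate 3 the symporter stood at 8.45 and acetyl-CoA synthetase at 7.68.

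Aminoacyl-tRNA synthetases and translation factors fell in 28 of 30 cases and rose in 0, also when adjusted over the list alone (camera adjusted p = 3.4e-08; adjusted p = 0.221 with an estimated correlation). Aspartyl-tRNA synthetase (PW_GM001264) had -2.28 ± 0.17 and elongation factor G -2.37 ± 0.23. Ribosomal protein genes fell in 38 of 51 cases and rose in 0, with 13 not past the test (42 and 0 when adjusted over the list alone; camera adjusted p = 3.67e-07; adjusted p = 0.543 with an estimated correlation). L31 (PW_GM002870) had -3.70 ± 0.40 and L27 (PW_GM002664) -2.79 ± 0.46. The list median was 9.03, 9.06 and 6.88 log2 CPM in untreated replicates 1 to 3, and 6.42, 5.97 and 7.36 in anaerobic replicates 1 to 3. Untreated replicate 3 thus lay under anaerobic replicate 3. Of 13 glycolysis and gluconeogenesis genes, 12 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.000106; adjusted p = 0.221 with an estimated correlation). Enolase had -2.46 ± 0.18. Phosphate uptake genes fell in 15 of 20 cases and rose in 3, also when adjusted over the list alone (camera adjusted p = 0.00153; adjusted p = 0.162 with an estimated correlation). The permease PW_GM002977 had -4.54 ± 0.37. Heat shock and protein quality genes fell in 15 of 26 cases and rose in 7, also when adjusted over the list alone (camera adjusted p = 0.00671; adjusted p = 0.552 with an estimated correlation). HtpG had -3.61 ± 0.22 and DnaK -3.09 ± 0.28. The median of this list was 6.05 and 6.08 log2 CPM in anaerobic replicates 1 and 2 and 6.92 in replicate 3.

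Flagellar and chemotaxis features rose in 59 of 98 cases and fell in 11 (59 and 13 when adjusted over the list alone; camera adjusted p = 7.46e-07; adjusted p = 0.543 with an estimated correlation). Without the 11 additional transcripts, 50 of 87 genes rose and 11 fell (camera adjusted p = 4.2e-05). Flagellin PW_GM000887 had a log2 fold change of 0.38 ± 0.36 and did not pass the test (adjusted p = 0.384). Anaerobic replicates 1 and 2 had 8952 and 12873 CPM of it, replicate 3 had 5466 CPM and the untreated libraries 6720 to 7350, and with untreated replicate 3 and anaerobic replicate 3 left out its log2 fold change was 0.84 and passed. The list of prophage and mobile elements had 9 of 10 members higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.000701; adjusted p = 0.162 with an estimated correlation). Again the examples are phage shock proteins: PspA (PW_GM000420) rose by 5.90 ± 0.51 and phage shock protein A (PW_GM001052) by 4.78 ± 0.39. Extracellular peptidases rose in 13 of 18 cases and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.0036; adjusted p = 0.31 with an estimated correlation). The subtilisin-type peptidases PW_GM002734 and PW_GM001941 rose by 5.83 ± 0.84 and 5.45 ± 0.86, and by 4.32 and 3.71 without anaerobic replicate 3. TonB-dependent receptors, which import scarce nutrients through the outer membrane, rose in 12 of 17 cases and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.0205; adjusted p = 0.221 with an estimated correlation; adjusted p = 0.0693 without untreated replicate 3). PW_GM001876 rose by 2.96 ± 0.29 and PW_GM001222 by 4.77 ± 0.52, the latter by 3.95 without anaerobic replicate 3. The list median was 6.20 and 6.01 log2 CPM in anaerobic replicates 1 and 2 but 5.24 in replicate 3, beside 5.04, 5.17 and 5.25 in the untreated libraries. In all, 2307 of 3909 features changed (59.0%), 1179 higher and 1128 lower. Of all 3909 features, called or not, 2317 (59.3%) had no overlap between the libraries of the groups, where chance gives 10%. Upper-quartile factors moved the median of all genes by 0.34 (log2) and gave 1537 higher and 882 lower.

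The changes against untreated overlapped between the conditions: 755 features rose in both, where independent calls would give 344, 868 fell in both, where independent calls would give 334, and 46 changed in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.793. The comparisons share their untreated libraries, and 20 simulated sets without any effect gave a mean r of 0.484 and a mean covariance of 0.0719, against an observed covariance of 2.76. With the untreated libraries parted between the comparisons in 6 ways on log2 CPM, a test chosen only after the result was seen, r was from 0.688 to 0.796. The counts of shared calls were not tested in this way.

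Respiratory genes were examined as lists whatever their test. The 11 terminal oxidase genes did not pass camera in any comparison (adjusted p = 0.0860, 0.351 and 0.861 in aerobic against untreated, anaerobic against untreated and anaerobic against aerobic). Against untreated, 6 fell and 1 rose under the aerobic condition (8 and 1 when adjusted over the list alone). Under the anaerobic one 5 fell and 2 rose (5 and 2 when adjusted over the list alone), where the median was 0.16, the mean -0.15 and the test direction lower. Without an assembly protein, removed after the product texts were seen, the median was -0.60. Subunit I of the cbb3-type oxidase (PW_GM001844), known for its high affinity for oxygen, had log2 fold changes of -2.26 ± 0.21 and -2.73 ± 0.21. A putative cytochrome c oxidase subunit I (PW_GM003407) rose by 3.84 ± 0.37 and 1.84 ± 0.34. In anaerobic against aerobic, 5 rose and 2 fell, also when adjusted over the list alone, with cytochrome c oxidase subunit I (PW_GM003076) at 2.27 ± 0.54.

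The nitrate and nitrite respiration list held 7 tested genes, of which 3 are NarL family sensors or regulators matched by words alone. In anaerobic against aerobic 3 rose and 0 fell, also when adjusted over the list alone, and camera gave an adjusted p of 0.486. Beside nitric oxide dioxygenase these were the nitrite reductase large subunit (PW_GM003320) with 2.52 ± 0.67 and a regulator of anaerobic nitric oxide reductase (PW_GM003088) with 1.34 ± 0.37. The call of PW_GM003320 was lost with limma-voom (2.15) and without aerobic replicate 1 (2.56), aerobic replicate 2 (2.30) or anaerobic replicate 1 (2.02). That of PW_GM003088 was lost without aerobic replicate 1 (1.28) or 3 (1.27) or anaerobic replicate 1 (1.24) or 2 (1.22). Against untreated, camera gave adjusted p of 0.85 (aerobic, 3 higher and 3 lower, also when adjusted over the list alone; median -1.08, mean -0.01, test direction higher) and 0.124 (anaerobic, 4 higher and 1 lower, also when adjusted over the list alone). Without the NarL members, 1 of 4 rose and 2 fell under the aerobic condition, with the test direction lower, and 2 rose and 0 fell under the anaerobic one.

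Other anaerobic reductases and fermentation genes gave camera adjusted p of 0.919, 0.865 and 0.425 in the same order of comparisons; in anaerobic against untreated the median was 0.36, the mean -0.08 and the test direction lower. Of 10 members, 4 rose and 4 fell in aerobic against untreated, also when adjusted over the list alone. In anaerobic against untreated 4 rose and 4 fell (5 and 4 over the list alone), and 1 rose and 3 fell in anaerobic against aerobic, also over the list alone. Acetate kinase (PW_GM001382) and phosphate acetyltransferase (PW_GM001381), which link acetyl-CoA and acetate, had log2 fold changes of -1.63 ± 0.16 and -1.47 ± 0.20 in anaerobic against aerobic, and D-lactate dehydrogenase (PW_GM001906) had -2.92 ± 0.33 in anaerobic against untreated. The list of the TCA cycle and glyoxylate shunt gave camera adjusted p of 0.367, 0.528 and 0.314. In aerobic against untreated 10 of 21 rose and 7 fell, also when adjusted over the list alone. In anaerobic against untreated 10 rose and 7 fell (11 and 8 over the list alone), and in anaerobic against aerobic 4 rose and 9 fell (4 and 10 over the list alone). The balance turned in the curated list of 12 enzymes of the cycle and shunt, made after the product texts were seen: 3 rose and 6 fell in aerobic against untreated (median -0.30, against 0.44 for the fixed list), 3 rose and 7 fell in anaerobic against untreated (median -0.98, against 0.77), and 2 rose and 6 fell in anaerobic against aerobic. Its camera adjusted p were 0.810, 0.198 and 0.266. The largest rises among the named genes of the fixed list lay outside the cycle: 2-isopropylmalate synthase (PW_GM003097) and 3-isopropylmalate dehydrogenase (PW_GM003096), enzymes of leucine synthesis, rose by 5.13 ± 0.54 and 4.98 ± 0.38 in aerobic against untreated. There 2-methylcitrate dehydratase (PW_GM001787), of propionate breakdown, rose by 4.09 ± 0.51. Oxidative stress defence gave camera adjusted p of 0.919, 0.865 and 0.905. Of 19 members, 8 rose and 9 fell in aerobic against untreated, 7 rose and 8 fell in anaerobic against untreated, and 5 rose and 4 fell in anaerobic against aerobic, with the same numbers when adjusted over the list alone. A peroxiredoxin of the alkyl hydroperoxide reductase family (PW_GM002143) had -4.57 ± 0.46 and -3.39 ± 0.43 against untreated, the latter -2.72 without untreated replicate 3.

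Among the calls in the authors' table, 537 higher and 499 lower features were tested here in anaerobic against aerobic, and 508 and 469 of them were called in the same direction with edgeR. In aerobic against untreated 983 of 1016 higher and 987 of 1021 lower calls were shared, and in anaerobic against untreated 512 of 513 and 641 of 641. In each comparison 0 features were called in opposite directions. The calls with edgeR were more numerous, at 1690, 2297 and 2307 features in anaerobic against aerobic, aerobic against untreated and anaerobic against untreated. Many of them, most of all in anaerobic against untreated, were therefore not among the authors' calls. The calls with edgeR had no minimum fold, and the test and threshold behind the authors' calls were not derived here. Whether the difference in number comes from the threshold or the tool was not tested.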

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

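Leaving out untreated replicate 3 and anaerobic replicate 3 together, and using coding gene models alone, were chosen only after the result was seen. Leaving out single libraries gave 1072 to 2301 genes in anaerobic against aerobic, 1984 to 2649 in aerobic against untreated, 1986 to 2607 in anaerobic against untreated, and 2622 to 3285 in the joint test. The lowest count came without aerobic replicate 1 (1072), followed by aerobic replicate 2 (1105), and the highest without anaerobic replicate 3 (2301). In anaerobic against aerobic, at least a 2-fold change left 1045 genes, and leaving out untreated replicate 3 and anaerobic replicate 3 gave 2900. The number of gene lists past the test was 4, 10 and 9 of 31 in anaerobic against aerobic, aerobic against untreated and anaerobic against untreated. It was 0, 0 and 0 with camera and an estimated correlation (0, 3 and 5 at an unadjusted p under 0.05), 13, 22 and 23 with fry, and 4 to 5, 10 to 11 and 9 to 11 without single libraries. None of the lists past the preset test passed with an estimated correlation. That correlation was 0.504 for ribosomal proteins and 0.252 for flagella and chemotaxis. It was 0.002 for phosphate uptake and -0.003 for TonB-dependent receptors, under the preset 0.01. The loss of the phosphate uptake and TonB-dependent receptor lists in this setting therefore cannot come from a higher correlation between genes. With the other settings, heat shock and protein quality in aerobic against untreated was lost without anaerobic replicate 3 (adjusted p = 0.0597), with a replicate block (0.052) and with both of those libraries left out (0.0944, as was the prophage list). Lost as well were TonB-dependent receptors in anaerobic against untreated without untreated replicate 3 (0.0693), and ribosomal proteins in anaerobic against aerobic with fry (0.122). The cause was not tested. The replicate block gave 1548, 2247 and 2232 genes. Deviations of libraries with the same number in different groups had r from -0.0374 to 0.05, so the numbers do not pair the libraries. DESeq2 gave 1899, 2431 and 2440 genes and limma-voom 1516, 2253 and 2240. Among 4133 alternative values for 199 pairs of a named gene and a comparison, 4027 kept direction and side of the threshold, 80 kept direction and no longer passed, 10 newly passed and 16 changed sign, 0 of these with a call in either setting. With single libraries left out, the log2 fold change of PW_GM001175 ran from -0.94 to 0.60 in aerobic against untreated and from -1.23 to 0.47 in anaerobic against untreated, that of PW_GM003997 from -0.40 to 0.23 in anaerobic against untreated, and that of an additional transcript from -0.45 to 0.83 in anaerobic against aerobic. With both libraries left out, PW_GM001175 had 0.60 and 0.088 in these comparisons, and additional transcripts had -0.30 and 0.11 in anaerobic against aerobic. With upper-quartile factors PW_GM001175 (0.012) and an additional transcript (0.10) in anaerobic against aerobic and PW_GM003997 (0.27) in anaerobic against untreated turned, the last also with at least 10 CPM in 3 libraries (0.043) and coding gene models alone (0.10). The cause was not tested. Between 62.7% and 100% of the calls were kept in the settings with a new fit, and 61.8% of those in anaerobic against aerobic with at least a 2-fold change. With coding gene models alone, the lists past the test numbered 4, 10 and 9 as well. With 100 simulated genes changed 2-fold, 28 to 34 percent were recovered. Far more features were called in the real comparisons (43.2% to 59.0%), which makes the adjusted threshold less strict there. The share of 2-fold changes missed in the real data was therefore not measured.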

Other observations

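The tests of short features as a class, of a swap of libraries, of additional transcripts parted by r, and of other splits of the libraries were chosen only after the result was seen, as were the runs of neighbouring genes, the Gene Ontology terms and the F-type ATPase list described first. In aerobic against untreated, 8 adjoining genes from PW_GM003501 to PW_GM003508 (bases 3901075 to 3913288), which encode a TonB-dependent receptor, TonB, ExbD and ExbB, fell with a median log2 fold change of -7.67, and in anaerobic against untreated with -6.17. All 8 F-type ATPase subunits fell against untreated, with medians of -3.36 (aerobic) and -2.36 (anaerobic), and 3 rose and 0 fell in anaerobic against aerobic (median 1.04). A run of 16 genes with a photolyase, a cyclopropane fatty acid synthase and a sigma-70 factor (PW_GM003589 to PW_GM003604) rose in aerobic against untreated (median 3.84), and 12 of its genes fell in anaerobic against aerobic (median -2.10). Genes PW_GM002620 to PW_GM002627, with a copper-exporting ATPase, rose in anaerobic against aerobic (8 genes, median 2.47). The run from PW_GM002620 to PW_GM002628 had fallen in aerobic against untreated (9 genes, median -2.86). Of 686 Gene Ontology terms, 7, 35 and 73 passed camera in anaerobic against aerobic, aerobic against untreated and anaerobic against untreated, with motility and locomotion terms alone in the first and translation as well in the comparisons against untreated, and 0 passed with an estimated correlation.

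The 93-base feature PW_GM002093 took up to 61.2% of a library. At least 92.3% of the calls of other genes were kept without the 20 most abundant features, so most calls did not depend on including them. Both fits used TMM factors, which already adjust for the weight of such features in the library totals. The test therefore says nothing about fits without such an adjustment. A better recovery of features of at most 400 bases as a class is argued against. Of such features without product text, 23 others with at least 0.05% of counts were compared in anaerobic against untreated. Their median log2 fold change was -0.01 (quartiles -1.15 and 1.00), where PW_GM002093 had 3.20, and the bound set for the test was 1.6. As the class reached 400 bases, a better recovery limited to features near 93 bases stays open. A response of this transcript to the named conditions stays open and was not tested.

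Untreated replicate 3 and anaerobic replicate 3 stood apart from their groups. A share of aerobic RNA as the only source of the distance of anaerobic replicate 3 is argued against. Of its 673 deviating features, 45.3% (305) lay outside the range to the aerobic level by over 0.5 log2. Such a share as part of the distance stays open. Anaerobic replicate 3 had r of 0.8773 to 0.8806 with the aerobic libraries, and anaerobic replicates 1 and 2 had 0.8311 to 0.8586. For untreated replicate 3, 57.1% of 606 deviating features (346) lay outside the range of the 3 groups by over 0.5. This argues against a share of RNA from the other libraries as the only source of its distance. A swap between groups is argued against, since 0 of the 9 libraries correlated best with a library of another group. A difference in growth state of the cells behind these libraries stays open and was not tested.

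Of 38 additional transcripts opposite a gene, 27 moved with it (r of at least 0.826, median 0.972) and 11 did not (r from -0.515 to 0.537), parted at r of 0.6. Over all 38 pairs, 28.9% correlated better with the nearest gene on the transcript's own strand. This argues against the pairs as a set being part of that gene's transcript, and single pairs were not tested. By part, it was 3 of the 27 pairs and 8 of the 11, so that origin stays open for the 11. Parting by r with the opposite gene by itself favours such a difference between the parts. Whether a fixed share of reads of the opposite gene was counted on the transcripts cannot be told apart from joint regulation over all pairs. The SD of the log2 ratio had a median of 0.64 (quartiles 0.471 and 1.465), between the bounds of 0.5 and 1 set for the test. Parting by r also favours a higher SD in the 11 pairs. The median was 0.551 (quartiles 0.443 and 0.763) in the 27 pairs, between the bounds, and 2.309 (1.446 and 2.982) in the 11, above them. Random pairs had 2.305.

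The 6 libraries of a pairwise comparison make 10 splits, the real one included, too few for a share under 0.05. Each split was fitted with those 6 libraries alone. The real counts were then 1757, 2554 and 1962 genes (anaerobic against aerobic, aerobic against untreated, anaerobic against untreated), and the highest of the other splits was 0. The fit of all 9 libraries gave 1690, 2297 and 2307, and these counts were not split. In the joint test, 1 of 100 splits drawn from 280 gave as many genes as the real 2923, the real one itself. The highest other gave 1762, so chance is unlikely there, though a sample of splits cannot exclude it.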
